A study of Alexandromys fortis with 18 samples.

How the data were processed

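Liver total RNA of Microtus fortis was profiled by Illumina RNA sequencing at days 0, 7, 10, 14, 21 and 28 of a Schistosoma japonicum infection, with 3 libraries per day and 18 libraries in all. Groups and replicate numbers were taken from the sample titles. Each library came as 1 table with a row per gene model, giving expected counts, TPM, FPKM, length and effective length. The expected counts are deposited RSEM estimates of the reads of each gene model and are not scaled for depth, per the file headers. TPM and FPKM are the deposited RSEM values scaled for length and depth by the authors, per the file headers, and TPM was used in 1 alternative while FPKM was not used in any test. The submitters' processing notes name CASAVA, RSEM without a version and the mouse build mm10. The deposited identifiers are numbered models on scaffolds, none of them a mouse identifier, so mm10 does not describe the models that were counted. The aligner, the read layout, the strand setting and the genome of the scaffolds are not given in the sources used here.

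All libraries listed the same 21867 gene models, of which 3207 had 0 counts in each library. None of the identifiers (0 of 21867) was found among the 29701 genes of the reference gene table, so no gene model was named. The gene lists, the cell type markers and the panel of genes fixed before the data were examined need gene names, and the tests of them were not run. The rule for naming took, per day, the 6 largest rises and 6 largest falls among called gene models with at least 10 CPM in the higher group and no overlap between the 3 and 3 libraries. Since no names were paired with identifiers, only the first 2 rises and 2 falls by this rule at day 14 are printed. Of the others, the 6 falls of day 10 are given as a range. Day 14 was chosen for this after the counts of calls were seen. Lengths are those of the gene models (78.5% are multiples of 3). Model positions, and reads shared between similar or overlapping models, were not resolved, so values of single models are uncertain where copies exist.

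Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Gene models were kept by filterByExpr at its defaults (minimum count 10, minimum total 15) with the 6 days as groups, which left 12343. Library sizes were scaled by TMM, dispersions were estimated robustly, and 1 quasi-likelihood fit on all 18 libraries served all comparisons, so the 6 groups shared 1 estimate of the spread. The comparisons were the joint test of 5 day coefficients, each later day against day 0 and the 4 steps between neighbouring days, with gene models called at a Benjamini-Hochberg adjusted p below 0.05. Log2 CPM values for correlations and principal components used a prior count of 2. Group values in CPM are TMM-scaled means with SD over 3 libraries, with 2 exceptions. CPM of the set of 54 gene models, and the CPM minimum of the alternatives, are per total counts. Median day 0 values of called groups were taken back from mean log2 CPM with the prior count of 2. Mean fragment length was computed as length minus effective length plus 1.

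Depth was 7657879 to 12044276 counts per library. A gene model with 0 counts over the 3 day 0 libraries was given a limit of 3 counts over the group, 0.114 CPM, and a gene model with 1 to 3 counts a ratio with an exact 95% binomial interval. These limits and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. On data simulated from these libraries with 12343 gene models, the test recovered 25%, 35%, 38%, 27% and 34% of models changed 2-fold at days 7, 10, 14, 21 and 28 against day 0, and 71%, 86%, 74%, 84% and 79% of those changed 4-fold. Of the simulated calls, 1.74% to 4.31% were false. The simulated counts follow the model of the test, with the same spread in each library, so this share need not hold for the real calls. Per simulation, 100 models were changed 2-fold and 100 changed 4-fold at 1 day, and the rest were unchanged. The adjusted threshold depends on how many models change, so the shares recovered need not hold for the real tests either.

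Alternatives fixed before the data were examined were DESeq2 size factors (RLE) in edgeR, no filter, a filter of at least 5 CPM in 3 libraries, unrounded counts, a replicate block, leaving out the 20 most abundant gene models, limma-voom and limma-trend on log2(TPM + 1) (limma 3.58.1), DESeq2 1.42.0, a fit on the 6 libraries of 2 days only, an added 2-fold minimum, and leaving out each library in turn. Alternatives added after seeing the data were a correction for gene model length (a lowess trend of span 0.5 per library, used as an offset), a minimum mean of 10 CPM, limma-voom with sample weights, and leaving out day 7 replicates 2 and 3. Overlaps between comparisons that share the day 0 libraries were set beside 20 simulations of unchanged groups. Reads were not analysed here.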

Results

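Liver RNA of the Yangtze vole Microtus fortis, a wild rodent listed in the labels under the name Alexandromys fortis, was sequenced during infection with Schistosoma japonicum. This parasite is a blood fluke whose larvae, the cercariae, enter through the skin, and the species is known as a host in which the fluke does not complete its development. The labels give a dose of 40 ± 1 cercariae and sampling at days 0, 7, 10, 14, 21 and 28, with 3 liver libraries per day and 18 in total. Day 0 served as the reference, and the comparisons asked which gene models changed at each later day and between neighbouring days. The dose is on the label of each library, day 0 included, and no uninfected group was sampled at the later days. Infection therefore cannot be told apart from anything else that changed with the day of sampling. The labels do not say that the 3 libraries of a day came from separate animals, so the p-values measure the spread between these samples only. The identifiers are numbers on genome scaffolds and the files do not pair them with gene names, so results are given as groups of gene models and for 4 identifiers.

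The libraries held 7657879 to 12044276 counts, and 13909 to 15995 of the 21867 gene models had counts in a library. The 6 libraries of days 14 and 21 and day 28 replicate 1 had 15648 to 15995, and the others 13909 to 15154. This division did not follow depth: day 21 replicate 3, with the lowest total, had 15766. The most abundant gene model, 1827 bases long, took 14.6% to 19.1% of the counts of each library, and the 10 most abundant took 26.7% to 33.4%. Mean fragment length, read from the deposited effective lengths, was 171.18 to 183.85 bases in the 9 libraries of days 0, 7 and 10 and 189.67 to 200.22 bases in the 9 libraries of days 14, 21 and 28. From the design alone, a library batch with this division cannot be told apart from the day of sampling. Correlations across gene models of log2 CPM (counts scaled to library size) averaged 0.969 within day 0, 0.934 within day 7, 0.966 within day 10, 0.980 within day 14, 0.982 within day 21 and 0.951 within day 28, and gene models are not independent replicates. The 3 day 7 libraries were the farthest apart, with pairs between 0.904 and 0.954. Day 28 replicate 1 had a mean correlation of 0.982 with the day 14 libraries, against 0.954 for replicate 2 and 0.949 for replicate 3. A repeated deposit of a library would give a chi-square per degree of freedom near or below 1 against the original, and the lowest value within a day was 8.36.

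**Figure D1:**
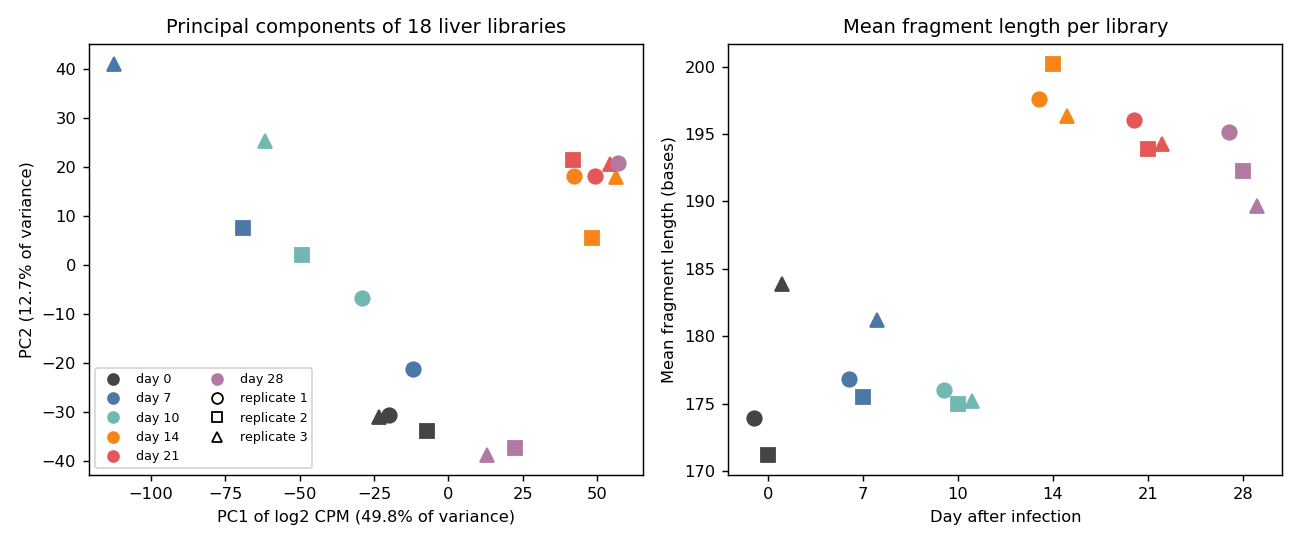
Principal components of log2 CPM over the 18 libraries (left) and mean fragment length in bases by day (right), with colours for days and symbols for replicates. The first component held 49.8% of the variance and the second 12.7%. All fragment lengths of days 14, 21 and 28 lie above 189 bases and all of days 0, 7 and 10 below 184.

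Over the whole time course, 5530 of the 12343 tested gene models (44.8%) differed between days. Of these, 3722 differed at least 2-fold between their highest and lowest day mean and 527 at least 4-fold. The highest mean fell at day 7, whose libraries were the farthest apart, for 2058 gene models, at day 28 for 1065, at day 21 for 885, at day 14 for 752, at day 0 for 441 and at day 10 for 329. Day 7 also held the most lowest means, 1524, against 1028 at day 10, 1007 at day 14, 855 at day 28, 567 at day 0 and 549 at day 21. A total of 2699 had their highest mean among days 14 to 28 and their lowest among days 0 to 10, and 2408 had the opposite order. Among the 1132 gene models with a mean of at least 100 CPM, 589 differed between days. The test was the joint edgeR quasi-likelihood F test of 5 day coefficients, with gene models called at a Benjamini-Hochberg adjusted p below 0.05, and the smallest adjusted p was 1.94e-05. The division between days 0 to 10 and days 14 to 28 is also that of fragment length.

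At day 7, 482 gene models were higher and 424 lower than at day 0, 906 in all. The median log2 change of those called was 0.93 for the higher and -1.04 for the lower, 199 rose and 230 fell at least 2-fold, and 21 rose and 16 fell at least 4-fold. The median length was 929.5 bases for the higher and 1797 for the lower, against 1302 for all tested gene models. In replicates 1, 2 and 3, models of up to 687 bases had median log2 differences from day 0 of -0.05, 0.32 and 0.58. Those of 2338 bases or more had 0.12, -0.43 and -0.67, so this trend with length lay in replicates 2 and 3. The largest rise was that of evm.TU.scaffold_31.377, a model of 411 bases with 0 counts in all 3 day 0 libraries and 135 ± 65.0 CPM (SD, n = 3) at day 7, at least 1189-fold above the limit of 0.114 CPM that 3 counts over the day 0 group allow. Its edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 0.00453. The number of calls depended on single libraries: without day 0 replicate 1, 2 or 3 it was 280, 64 or 111, and without day 7 replicate 1, 2 or 3 it was 5215, 483 or 113. Which direction held more calls turned with the setting. Lower calls were more with limma-voom (291 higher, 429 lower) and with the replicate block (392, 442). They were also more without day 7 replicate 1 (2335, 2880) or 3 (51, 62) and without day 0 replicate 1 (124, 156) or 3 (48, 63). The same held with limma-voom sample weights (2243, 2804), chosen after the data were seen. DESeq2 called 2151 with 61.2% higher, limma-trend on log2(TPM + 1) 356 with 72.2% higher, and a fit on the 6 libraries of these days alone called 1.

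At day 10, 186 gene models were higher and 259 lower than at day 0. The median log2 change was 1.28 for the higher and -1.14 for the lower, and 135 rose and 162 fell at least 2-fold. The lower gene models were long, with a median of 2311 bases against 1242 for the higher. The model evm.TU.scaffold_31.377 stood at 105 ± 18.4 CPM (SD, n = 3), at least 919-fold above the day 0 limit, with an adjusted p of 0.00375 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, against 0.0531 with limma-voom and sample weights. The 6 largest falls that met the naming rule had log2 changes between -3.77 and -2.10. Leaving out day 0 replicate 1, 2 or 3 gave 175, 48 or 187 calls, and leaving out day 10 replicate 1, 2 or 3 gave 258, 162 or 69. Higher calls were more without day 10 replicate 2 (105 higher, 57 lower) or 3 (47, 22) and without day 0 replicate 2 (25, 23), so the direction with more calls rests on single libraries. DESeq2 called 1047, and limma-trend on log2(TPM + 1) gave 89.2% higher calls against 41.8% here.

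At day 14, 615 gene models were higher and 504 lower than at day 0, the most calls of any day against day 0 in this fit. The higher gene models rose by more: their median log2 change was 1.78 against -0.88 for the lower, and 257 rose and 35 fell at least 4-fold. They also started from low levels, with a median day 0 value of 1.83 CPM against 26.9 CPM for the lower. Their median length was 1737 bases against 1134 bases for the lower, on the same days on which fragments were longer. Over all tested gene models the Spearman correlation of log2 change with length was 0.30 at day 14. It was -0.30 at day 7 and -0.28 at day 10, where mean fragment lengths of 177.85 and 175.38 bases were near the 176.32 of day 0. Trends with length therefore arose without longer fragments too. A set of 54 gene models held 47 of the higher calls. It was chosen after its values were seen, as near 0 at days 0 and 7 and at least 3 CPM on average at day 14. Its summed counts were 5532 to 6517 in the day 14 libraries against 50 to 80 at day 0, a rise that the choice itself brings about.

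Of the gene models named by the rule at day 14, evm.TU.scaffold_51.28 (942 bases) had 3 counts in all at day 0 and 119 ± 27.9 CPM (SD, n = 3) at day 14, a ratio of TMM-scaled counts of 1020 with an exact 95% counting interval of 349 to 4949. The rise had an adjusted p of 0.0260 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and the model belongs to the set of 54. The model evm.TU.scaffold_31.377 was at 25.1 ± 16.6 CPM, at least 221-fold above the day 0 limit, with an adjusted p of 0.00539 by the same edgeR test with Benjamini-Hochberg adjustment. The largest fall was that of evm.TU.scaffold_307.9 (836 bases), from 94.5 ± 35.3 CPM at day 0 to 3.19 ± 0.673 CPM (SD, n = 3 each), a log2 change of -4.89 (SE 1.27) with an edgeR Benjamini-Hochberg adjusted p of 0.0308. This model also varied within days, with 1084, 688 and 0 counts in day 10 replicates 1, 2 and 3. At day 28 it was at 61.0 ± 34.7 CPM (edgeR Benjamini-Hochberg adjusted p against day 0 of 0.733). The model evm.TU.scaffold_221.92 (1932 bases) fell from 19.8 ± 4.80 CPM to 3.36 ± 0.371 CPM (SD, n = 3 each), a log2 change of -2.55 (SE 0.30) with an edgeR Benjamini-Hochberg adjusted p of 0.000296. The call of evm.TU.scaffold_51.28 was lost without day 0 replicate 1, 2 or 3 or without day 14 replicate 2 or 3, with edgeR Benjamini-Hochberg adjusted p of 0.0849, 0.0806, 0.0920, 0.0527 and 0.0698, and without a filter (0.0556). The call of evm.TU.scaffold_307.9 was lost without any 1 of the 6 libraries, with edgeR Benjamini-Hochberg adjusted p of 0.0540 to 0.103, with limma-voom (0.146), with limma-voom and sample weights (0.0772), with limma-trend on log2(TPM + 1) (0.0555) and without a filter (0.0638). That of evm.TU.scaffold_31.377 was lost with limma-voom (Benjamini-Hochberg adjusted p 0.0601), with limma-voom and sample weights (0.0861) and with edgeR on the 6 libraries of these days (0.0887), and that of evm.TU.scaffold_221.92 held in all 20 alternatives run for it, with adjusted p up to 0.0109.

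**Figure D2:**
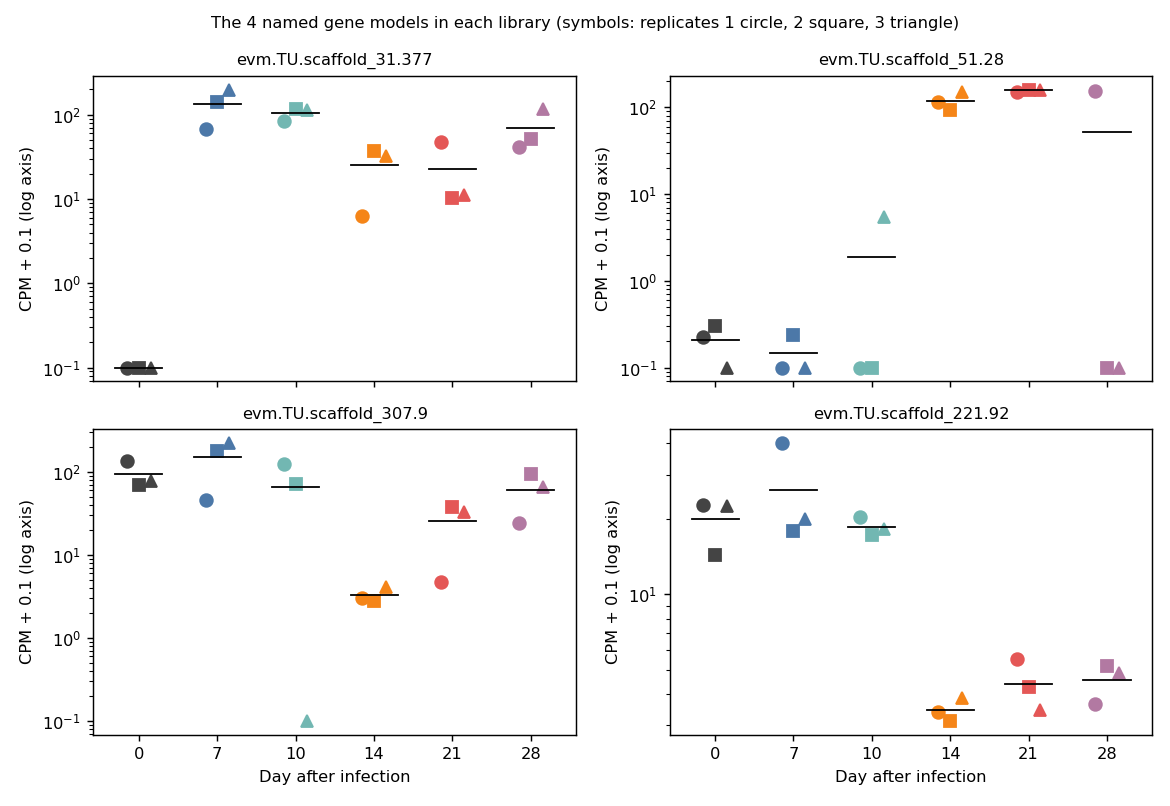
CPM + 0.1 on a log axis in each library for the 4 named gene models, by day after infection, with symbols for replicates and bars for the day mean. The model evm.TU.scaffold_31.377 was at 0 in the day 0 libraries and at 5 CPM or more in the other 15. The model evm.TU.scaffold_51.28 was at 155.9 CPM in day 28 replicate 1 and at 0 in replicates 2 and 3.

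The counts of calls at day 14 also depended on single libraries. Without day 0 replicate 1, 2 or 3, 358, 420 or 330 gene models were called, and without day 14 replicate 1, 2 or 3, 487, 343 or 185. Without day 7 replicates 2 and 3, a choice made after the data were seen, the count was 3293. Lower calls were more without day 0 replicate 1 (149 higher, 209 lower), 2 (165, 255) or 3 (113, 217), without day 14 replicate 3 (83, 102), without day 7 replicates 2 and 3 (1626, 1667), among gene models with at least 5 CPM in 3 libraries (380, 384), and among those with a mean of at least 10 CPM (192, 302), a minimum also chosen after the data were seen. On the log2(TPM + 1) scale the median of all tested gene models moved by 0.36 from day 0 to day 14, against 0.04 with TMM scaling, and 93.9% of the limma-trend calls were higher against 55.0% here.

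At day 21, 604 gene models were higher and 407 lower than at day 0. The median log2 change was 1.95 for the higher and -0.83 for the lower, and 295 rose and 19 fell at least 4-fold. The higher gene models had a median day 0 value of 1.44 CPM and the lower 30.7 CPM, and their median lengths were 1700 and 1235 bases. The model evm.TU.scaffold_51.28 reached 156 ± 4.38 CPM (SD, n = 3), 1370 times its day 0 level with an exact 95% counting interval of 469 to 6647, and an edgeR Benjamini-Hochberg adjusted p of 0.0238. The model evm.TU.scaffold_31.377 was at 22.7 ± 20.9 CPM, at least 199-fold above the day 0 limit, with an edgeR Benjamini-Hochberg adjusted p of 0.00699. The model evm.TU.scaffold_221.92 was still at 4.30 ± 1.03 CPM, a log2 change of -2.19 with an edgeR Benjamini-Hochberg adjusted p of 0.00128, while evm.TU.scaffold_307.9 was at 4.67, 37.9 and 33.1 CPM in the 3 libraries with an edgeR Benjamini-Hochberg adjusted p of 0.286. Of the set of 54 models near 0 at days 0 and 7, 49 were called higher. Leaving out day 0 replicate 1, 2 or 3 gave 245, 337 or 232 calls, leaving out day 21 replicate 1, 2 or 3 gave 269, 355 or 168, and leaving out any of the 6 ended the call of evm.TU.scaffold_51.28 (edgeR Benjamini-Hochberg adjusted p 0.0502 to 0.0885). That of evm.TU.scaffold_31.377 was lost with limma-voom (Benjamini-Hochberg adjusted p 0.0695), with limma-voom and sample weights (0.1005) and with edgeR on the 6 libraries of these days (0.108). Lower calls were more without day 0 replicate 2 (153 higher, 184 lower) or 3 (98, 134), without day 7 replicates 2 and 3 (1409, 1449) and among gene models with a mean of at least 10 CPM (155, 228). On the log2(TPM + 1) scale, where the median of all tested gene models moved by 0.30, 93.4% of the limma-trend calls were higher against 59.7% here.

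At day 28, 258 gene models were higher and 422 lower than at day 0. The median log2 change was 1.26 for the higher and -0.93 for the lower, and 51 rose and 38 fell at least 4-fold. The median length was 1695.5 bases for the higher and 1239 bases for the lower. The model evm.TU.scaffold_31.377 was at 69.5 ± 40.1 CPM (SD, n = 3), at least 610-fold above the day 0 limit, and evm.TU.scaffold_221.92 at 4.45 ± 0.790 CPM, a log2 change of -2.15, with edgeR Benjamini-Hochberg adjusted p of 0.00145 and 0.00106. The call of evm.TU.scaffold_31.377 was lost with limma-voom and sample weights (Benjamini-Hochberg adjusted p 0.0729). The model evm.TU.scaffold_51.28 had 1361 counts in replicate 1 and 0 in replicates 2 and 3, and its edgeR Benjamini-Hochberg adjusted p was 0.0538. The edgeR Benjamini-Hochberg adjusted p passed the threshold without replicate 2 (0.0308) or 3 (0.0268), with at least 5 CPM in 3 libraries (0.0394) and with a mean of at least 10 CPM (0.0362), as did that of DESeq2 (0.0184). Without replicate 1 the log2 change was -3.23 (edgeR Benjamini-Hochberg adjusted p 0.710), and the Benjamini-Hochberg adjusted p with limma-voom sample weights was 0.879. The 3 libraries of this day were unlike in the gene models that had risen by day 14. The 615 higher calls of day 14 had a median log2 difference from day 0 of 1.73 in day 28 replicate 1, 0.69 in replicate 2 and 0.66 in replicate 3. Of these 615, 228 reached at least 0.5 of their day 14 log2 rise in all 3 day 28 libraries and 256 in replicate 1 alone. The 504 lower calls of day 14 were alike in the 3 libraries, with medians of -0.86, -0.78 and -0.76, and 409 reached at least 0.5 of their log2 fall in all 3. Leaving out day 28 replicate 1, 2 or 3 gave 317, 449 or 487 calls (the last with 243 higher and 244 lower), and leaving out day 0 replicate 1, 2 or 3 gave 284, 389 or 242. DESeq2 called 1322, of which 52.3% were higher against 37.9% here, and limma-trend on log2(TPM + 1), with a median of all tested gene models of 0.31, gave 84.2%.

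**Figure D3:**
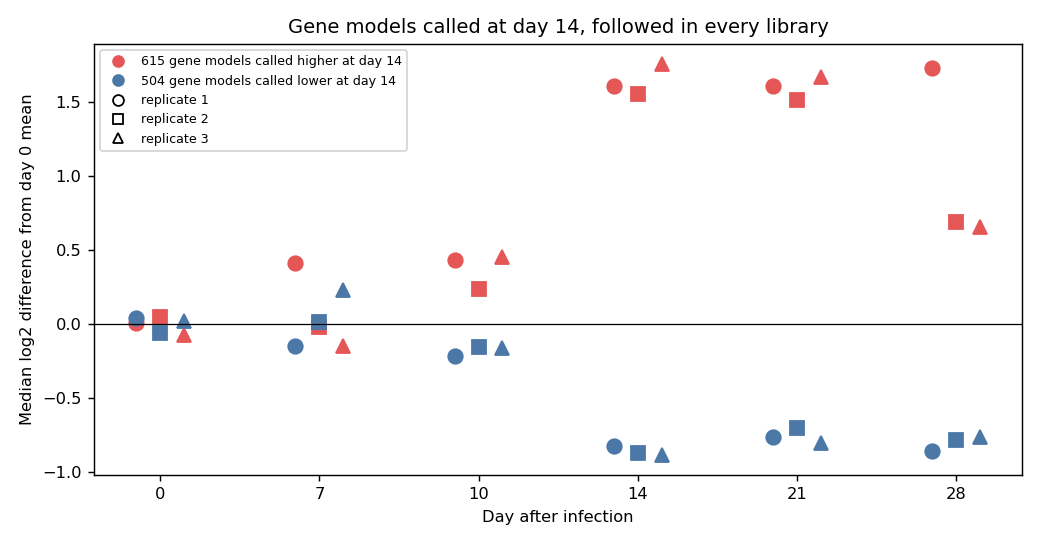
Median log2 difference from the day 0 mean in each library, for the 615 gene models called higher (red) and the 504 called lower (blue) at day 14, by day after infection and with symbols for replicates. The higher group stood at 1.51 to 1.76 in the libraries of days 14 and 21, and at 1.73 in day 28 replicate 1 against 0.69 and 0.66 in replicates 2 and 3.

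Between neighbouring days, the calls of this fit came from the step between days 10 and 14 alone. Mean fragment length was at most 176.03 bases at day 10 and at least 196.36 bases at day 14. A library batch with this division cannot be told apart from this step as a whole. For the 615 higher calls of day 14 against day 0, such a batch as the whole cause is argued against. Day 28 replicates 2 and 3 had long fragments too (192.23 and 189.67 bases). Median log2 differences of these calls were 0.69 and 0.66 there, against 1.51 to 1.76 at days 14 and 21. The 504 lower calls stood at -0.78 and -0.76 there, so a batch stays open for them. From day 10 to day 14, 2265 gene models rose and 1487 fell, 3752 in all (30.4% of those tested). Of these, 1662 rose and 468 fell at least 2-fold, and 482 rose and 38 fell at least 4-fold. The median length was 2118 bases for those that rose and 765 bases for those that fell. Across all tested gene models the Spearman correlation of the log2 change with model length was 0.42, with a median log2 change of -0.44 for models of up to 687 bases and 0.60 for those of 2338 bases or more. A correction for length, chosen after the data were seen, called 1765 rises and 1205 falls, among them 1570 of the rises and 838 of the falls above. It moved the median log2 change of the 1487 falls from -0.84 (SD 0.51 over gene models) to -0.61 (SD 0.54). Without day 10 replicate 2 or 3, 1917 or 1500 gene models were called, and without day 14 replicate 2 or 3, 2155 or 1886. On the log2(TPM + 1) scale, where the median of all tested gene models moved by 0.34, 84.7% of the limma-trend calls were rises against 60.4% here.

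The other steps gave no calls in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. From day 7 to day 10 the smallest adjusted p was 0.0584, with 960 gene models at an unadjusted p under 0.05; DESeq2 called 29, limma-voom 0 and limma-trend on log2(TPM + 1) 2. Without day 7 replicate 1, 865 gene models were called. From day 14 to day 21 the smallest edgeR Benjamini-Hochberg adjusted p was 1.00, with 102 gene models at an unadjusted p under 0.05, and DESeq2, limma-voom and limma-trend called 0. From day 21 to day 28 the smallest edgeR Benjamini-Hochberg adjusted p was 0.313, with 460 gene models at an unadjusted p under 0.05; DESeq2 called 2, limma-voom 0 and limma-trend 0. Without day 28 replicate 1, 331 gene models were called between days 21 and 28.

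**Figure D4:**
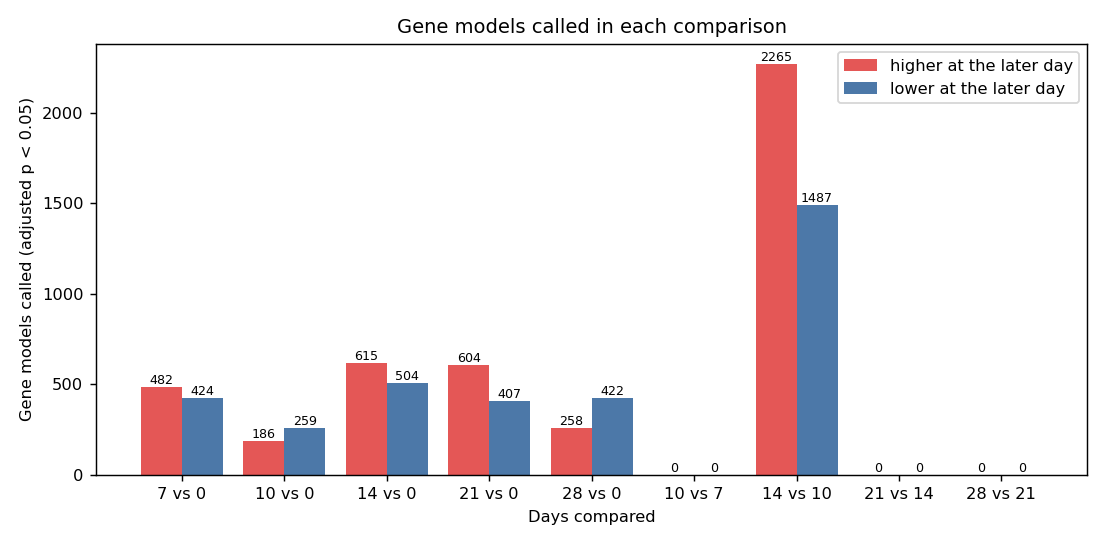
Number of gene models called at an edgeR Benjamini-Hochberg adjusted p below 0.05 in each comparison, higher (red) and lower (blue) at the later day, 3 libraries per day. Bars for day 10 against 7, 21 against 14 and 28 against 21 are at 0, and those for day 14 against 10 are at 2265 and 1487. Fragment length also changed between days 10 and 14, so a library batch cannot be told apart from that step as a whole.

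Across days, 2414 gene models were called against day 0 at 1 or more days. Of these, 1275 were called at exactly 1 day, 19 were higher and 19 lower at all 5 days, and 53 were called in opposite directions at different days. Higher calls shared by days 14, 21 and 28 numbered 138 and lower calls 241, and those shared by days 7 and 10 numbered 92 and 127. Days 14 and 21 shared 450 higher and 319 lower calls, against 30.1 and 16.6 for independent lists. Shared calls averaged 0 in 20 simulations of unchanged groups against the same controls, which does not measure what the controls add between lists of real calls. The correlation of their log2 changes across gene models was 0.953, against 0.507 in the simulations, and the covariance 0.932 against 0.094. For days 7 and 10 the correlation was 0.689 against 0.498, and the covariance 0.383 against 0.095. For days 7 and 14, 42 higher and 36 lower calls were shared and 40 were opposite, with a correlation of 0.082 against 0.507 and a covariance of 0.060 against 0.095. The 3 day 0 libraries are too few to divide, so part of the excess may come from the shared controls.

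None of the 10 most abundant gene models was called against day 0 at any day by edgeR, and in the joint edgeR test 2 of them had a Benjamini-Hochberg adjusted p below the threshold (0.00764 and 0.0398). The fifth most abundant, 585 bases long, varied from 25 counts in day 28 replicate 3 (0.000265% of the library) to 3.79% of the counts in day 0 replicate 3, and had a joint edgeR Benjamini-Hochberg adjusted p of 0.564.

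**Figure D5:**
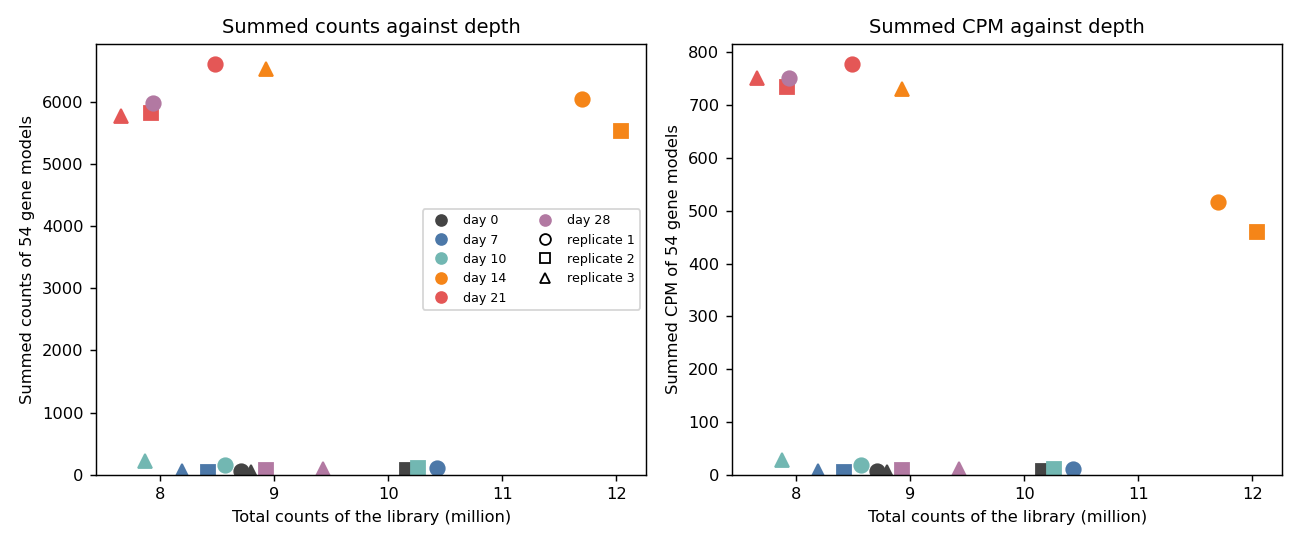
Summed counts (left) and summed CPM (right) of the 54 gene models near 0 at days 0 and 7, against the total counts of the library, with colours for days and symbols for replicates. The set was chosen to average at least 3 CPM at day 14, so its rise there follows from the choice. The 6 libraries of days 14 and 21 and day 28 replicate 1 lie between 5532 and 6597 counts, and the other libraries between 42 and 227.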

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

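The alternatives with a length correction, a mean of at least 10 CPM, sample weights and without day 7 replicates 2 and 3 were chosen only after the data were seen. Of the counts of calls, 138 values stayed within 1.5 times the count given in the results and 80 did not. Of the values of the 4 named gene models, 352 kept their direction and side of the threshold, 30 lost the call, 5 gained one and 9 turned sign, all of them uncalled in both settings. With limma-voom sample weights, the log2 change was 0.21 for evm.TU.scaffold_51.28 and -0.0244 for evm.TU.scaffold_221.92 at day 7, and -0.0424 for evm.TU.scaffold_51.28 at day 10. Leaving out 1 library at a time gave log2 changes of -0.0703 to 0.62 for evm.TU.scaffold_221.92 at day 7 and -0.29 to 0.0302 at day 10, -3.25 to 4.45 for evm.TU.scaffold_51.28 at day 10 and -3.23 to 9.43 at day 28, and -1.39 to 0.0631 for evm.TU.scaffold_307.9 at day 10. The call of evm.TU.scaffold_221.92 held at days 14, 21 and 28 in all alternatives run. That of evm.TU.scaffold_31.377 was lost at days 14 and 21 with limma-voom (Benjamini-Hochberg adjusted p 0.0601 and 0.0695) and with edgeR on 6 libraries (0.0887 and 0.108), and with limma-voom sample weights at days 10, 14, 21 and 28 (0.0531, 0.0861, 0.1005 and 0.0729). The gene list tests and their alternatives were not run, because the identifiers carry no gene names. At this depth and replication, 25% to 38% of simulated 2-fold changes against day 0 were recovered, so changes of that size can stay uncalled. The share depends on how many models change, and the simulations changed few. The spread of the day 7 libraries enters the shared estimate of spread in each comparison. The cause of the moves below was not tested, except that an added 2-fold minimum lowers a count by construction.

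Leaving out 1 library at a time gave 64 to 5215 calls at day 7 against day 0 (lowest without day 0 replicate 2, highest without day 7 replicate 1), 48 to 258 at day 10, 185 to 487 at day 14, 168 to 355 at day 21, 242 to 487 at day 28, 4665 to 7552 in the joint test, 0 to 865 from day 7 to 10, 1500 to 3601 from day 10 to 14, 0 from day 14 to 21 and 0 to 331 from day 21 to 28.

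For day 7, 10, 14, 21 and 28 against day 0, sample weights gave 5047, 2439, 4109, 3586 and 2234 calls, the 6-library fit 1, 1033, 3557, 3218 and 1416. Without day 7 replicates 2 and 3, where the 1 library left is assumed to vary like the other groups, days 10, 14, 21 and 28 gave 2677, 3293, 2858 and 2640. DESeq2 gave 2151 at day 7, 1047 at day 10 and 1322 at day 28. No filter gave 530 and limma-trend on log2(TPM + 1) 356 at day 7. An added 2-fold minimum gave 429, 709, 656 and 357 at days 7, 14, 21 and 28, and a mean of at least 10 CPM gave 286, 494 and 383 at days 10, 14 and 21. From day 10 to 14 the counts were 2130 with the 2-fold minimum, 2257 with at least 10 CPM, 6332 with sample weights and 5752 without day 7 replicates 2 and 3, and in the joint test 3311 with at least 10 CPM and 8538 with sample weights. From day 7 to 10 they were 1 each with RLE, no filter and the 20 most abundant models left out, 2 with limma-trend, 29 with DESeq2, 4 with the length correction and 414 with sample weights. From day 14 to 21 the 6-library fit gave 4, and from day 21 to 28 DESeq2 gave 2 and sample weights 356.

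The labels do not say what the libraries of a replicate number share. Among 45 same-number pairs of libraries, 5 had a correlation of deviations over 0.1, with a highest of 0.40. The mean was 0.0056 against -0.0028 for other numbers, and 8 of 18 libraries matched best with their own number. This does not exclude an animal or batch shared by some libraries of a number. With the replicate block, the counts were 834, 452, 1175, 996 and 634 at days 7, 10, 14, 21 and 28 against day 0, 3894 from day 10 to 14 and 5566 in the joint test, and 0 in the other steps, and no count moved by over 1.5 times. At day 7 the block gave 392 higher and 442 lower calls, against 482 and 424.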

Other observations

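The tests chosen only after the result was seen were those of reads from another sample, of a depth-independent liver response, of the length trend and library batch behind the day 14 falls, and of sequencing depth at day 7. The set of 54 gene models was chosen in the same way, as was the use of the spread of pairs in the length test at day 7.

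Gene models with consecutive identifiers were called in the same direction more often than in shuffled calls. Identifiers number the models along each scaffold if they follow the usual order, which was assumed and not tested. Among 5875 pairs of consecutive tested models, 49 pairs were called in the same direction at day 14 against a mean of 24.3 in 10000 shuffles of the calls, and 17 pairs were called in opposite directions against 24.0. Same-direction pairs numbered 35 at day 7, 16 at day 10, 36 at day 21 and 30 at day 28, against shuffled means of 15.8, 3.87, 20.4 and 9.43. The permutation p was 1e-04 at days 7, 10, 14 and 28, the smallest the shuffles can give, and 9e-04 at day 21, with Benjamini-Hochberg adjusted values of 0.00012 and 9e-04 over the 5 days. Copies of 1 gene that share reads, genes in families and genes with shared control are open and were not told apart.

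A set of 54 gene models was at no more than 0.5 CPM in each day 0 library, no more than 1 CPM in each day 7 library and at least 3 CPM on average at day 14. Its summed counts in the 6 libraries of days 14 and 21 varied less (CV 7.12%) than its summed CPM (CV 20.7%), although the library totals spanned 1.57-fold. Only 0.03% of 10000 random lists matched on expression had counts as steady. These lists were matched on mean and not on variability, and their counts followed depth (median CV 18.9%, against 4.24% for their CPM). Any set with lower CPM in the 2 deepest libraries could pass, and this set had 517 and 459 CPM there against 730 to 777 in the others. A similar number of reads of another sample may have been added to each of these libraries, but the test does not show it. Over the 6 libraries the Pearson correlation of log2 summed CPM with log2 total was -0.953 (exact permutation p 0.0208, Benjamini-Hochberg 0.0417 over both coefficients) and Spearman's rho -0.829 (exact permutation p 0.0583, Benjamini-Hochberg 0.0583), but it rests on the 2 libraries farthest in depth, without which r was -0.08. Against a liver response that is unrelated to depth, 0% of the random lists had summed CPM as unsteady (highest CV 14.99%), but livers that differ in their response would vary in this way too, so it stays open, and the 6 libraries cannot tell these explanations apart. The steady counts, the unsteady CPM and the correlation rest on the same 2 deepest libraries and are not separate evidence. Day 28 replicate 1 held 5970 counts of the set against 85 and 100 in replicates 2 and 3, and a wrong label of that library and parasite reads assigned to vole models were not tested. That library and the 6 of days 14 and 21 also had more gene models with counts, 15648 to 15995 against 13909 to 15154 in the others. The division is therefore not limited to the 54.

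The 504 gene models called lower at day 14 were shorter than the rest, and fragments were longer in those libraries. Trends with length in the other direction arose at days 7 and 10, where mean fragment lengths were near that of day 0. After the correction for length, 435 of the 504 stayed called lower and their median log2 change went from -0.88 (SD 0.57 over gene models) to -0.82 (SD 0.59). The 504 were selected by their fall and the correction removes the average trend only, so a loss of most calls was unlikely beforehand. That trend was small, with a median of -0.24 over all tested models of up to 687 bases. Its size argues against the average length trend as the whole cause. Length effects that differ between models were not tested. A library batch shared by days 14, 21 and 28 cannot be told apart from the infection, because the shortest mean fragment length of these days lies 5.82 bases above the longest of days 0, 7 and 10 and no day has libraries on both sides. A response of the liver to the infection stays open, as does a batch. Other differences between the days of sampling stay open too, since no uninfected group was sampled at the later days.

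The 3 day 7 libraries lay far apart, with a mean correlation of 0.934. Lower depth is argued against, since the 3 day 21 libraries, with 7657879 to 8486535 counts against 8194251 to 10423850 at day 7, correlated at 0.982 or more, above the highest day 7 pair at 0.954. The correction for length raised the mean to 0.943, below the 0.951 of day 28, the lowest of the other days. By the rule fixed before the result was seen, this goes against a length trend as the whole cause. The distance is within the spread of the corrected day 7 pairs (SD 0.0200, n = 3 pairs), a comparison added afterwards. These pairs share libraries, so their SD does not measure the error of the mean, and a length trend is not excluded. A difference between the sampled livers in the course of the infection stays open and was not tested.

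Chance as the source of the calls was examined with other splits of the same libraries. For the joint test, 1 of 100 splits of the 18 libraries, the real one, called as many as 5530 gene models and the highest other split called 3512. Chance assignment of libraries to days is argued against there, at the resolution of 100 splits. A library batch that follows the days would exceed the other splits as well, so the splits do not test the infection. Splits of 3 against 3 libraries number only 10, too few for a share under 0.05. The highest other split called 0 at day 10 (real 445), day 14 (1119), day 21 (1011) and day 28 (680) against day 0 and from day 10 to day 14 (3752), where 1 of 10 splits reached the real count. For day 7 against day 0, 2 of 10 splits called as many as the real 906, and the other called 1427, with day 0 replicates 1 and 2 and day 7 replicate 1 against the rest. For days 7 and 10, where the real count was 0 and 10 of 10 splits reach it by definition, the split of day 7 replicate 1 and day 10 replicates 1 and 2 against the rest called 2779 and the other 9 called 0. That split was singled out after its count was seen, so it points to a structure of these samples other than the day without a test of it. For days 14 and 21 and for days 21 and 28 the real count was 0, which 10 of 10 splits reach by definition, and the highest other split called 0, so the splits test nothing there.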
